A study of Mus musculus with 41 samples.

How the data were processed

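Guide DNA from pooled CRISPR-Cas9 screens was counted in 41 mouse libraries, 16 from cultured neural stem cells and 25 from brain tissue. The deposited files are whole-number counts per guide, with a line for each guide and no header. Per the labels' protocols, guides were amplified from genomic DNA in 2 nested rounds of PCR, the first with 19 cycles. The second round had 30 cycles for screen 1 in culture and for the in vivo screens, and 18 cycles for screens 2 and 3 in culture. Screen 1 was amplified with Herculase II polymerase, and screens 2 and 3 and the in vivo screens with Q5 polymerase, per the labels' protocols. The genome build is mm10, per the submitters' processing notes; the aligner or guide counter is not given in the sources used here. No molecular identifiers are described, so reads are not independent molecules, and intervals on shares of counts (95% Wilson) cover counting error only.

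Guides that a file does not list were given a count of 0. The files of the genome-wide screens together named 242113 guides, of which 227164 target 22906 genes (a median of 10 guides per gene), 7473 are non-targeting controls and 7476 are safe-targeting controls, which are directed at sites outside genes. Guide names carry an Ensembl gene ID, a symbol and 1 of 20 cloning pools. Coordinates are those of the GRCm38.p6 assembly in a RefSeq gene table, which held 20566 of the 22819 symbols. The in vivo sublibraries held guides for 10 genes each and 100 safe-targeting controls.

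Total counts ranged from 8974687 to 42438223 per library in culture (median 23625952) and from 209171 to 2489444 in vivo (median 738560). With medians of trended negative binomial dispersion of 0.29 for summed genes and 1.42 for single guides, the spread between libraries adds to the counting error, which is largest where guides have a median of 1 to 5 counts, in culture and in vivo.

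Groups were taken from the sample titles. The 16 libraries in culture entered 1 fit, since the old quiescent cells and the guide library have 1 library each. Their spread is assumed to be like that of the other groups. Comparisons set reactivated cells (day 14) and Ki67-positive cells (day 4) against quiescent cells, with young and old averaged and for each age, old against young, reactivated against Ki67-positive, and quiescent against the guide library, 10 in all. The labels speak of biological replicates in the growth protocol but do not say which animals or cultures each screen came from, so p-values measure only the spread between these samples. The tests, the alternatives planned and the gene lists were fixed before the data were examined.

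Each comparison in culture had a pair of tests. In the summed-count test, counts were summed over the guides of a gene and tested with edgeR 4.0.16 (quasi-likelihood, filterByExpr, TMM scaling) over 22906 genes. In the guide-set test, each guide was tested with edgeR, its p was turned into a signed normal score, and the mean score of a gene with at least 4 guides was set against 1000000 random draws of as many control guides (two-sided), over 22849 genes. The smallest p this can give is 2e-06. The guide-set test asks whether the guides of a gene move together more than control guides do in these libraries; it does not carry the spread of a gene's effect between libraries. A log2 change of a gene is the median over its guides minus that of the control guides, with the SD over guides. Benjamini-Hochberg adjustment ran over genes within a comparison, with a threshold of 0.05.

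Gene lists, 26 in all with at least 5 measured genes, were tested in the first 8 comparisons with fry and camera (limma 3.58.1) on the summed counts, adjusted over lists within a comparison. The p of fry tests whether the genes of a list move on balance one way, and neither test of fry compares a list with other genes. The lists cover essential machinery (cytosolic and mitochondrial ribosome, proteasome, spliceosome, DNA replication, mitosis, RNA polymerases, tRNA synthetases, respiratory chain, cholesterol synthesis), signalling and cell cycle control, glucose handling, the cilium, ribonucleoprotein granules, lysosome and autophagy, neural stem cell regulators, and olfactory receptor genes as genes with no known role in these cells.

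In vivo, guides were compared between the olfactory bulb and the subventricular zone at 24 h for 5 sublibraries, and between Top10 bulbs of mice labelled WT and of the other mice. Counts plus a pseudocount of 1 were put on the log2 scale and centred per library on the median of the control guides. The guides of a gene were then set against the control guides by a two-sided permutation test (exact under 100000 arrangements, otherwise 100000 resamples), adjusted over the 50 genes of the sublibraries and, for the WT comparison, over its own 10. Such a p describes these libraries and not mice in general. Guides were also tested one by one with edgeR, scaled on the control guides. Single libraries of other tissues were described without a test.

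The genes named per comparison and direction are up to 10 with the smallest summed-count p past the threshold with a guide-set p under 0.05 in the same direction, filled up to 10 by the smallest guide-set p among genes past the guide-set threshold whose summed change has the same sign. Up to 4 members per gene list and direction were added, with Slc2a4 and each sublibrary gene past either threshold. In vivo the rule takes every gene past the threshold and the 3 highest and 3 lowest of each sublibrary. Some genes that the rule names are not reported here.

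Replicate numbers in culture are screen numbers. The labels tie screen 1 to another polymerase and number of PCR cycles than screens 2 and 3, which share theirs. The number thus marks a batch only in part. Codes in the sample titles differ between young and old libraries of the same screen. Age and such a code cannot be told apart in the comparisons of old with young cells. Deviations from the group means correlated with a median r of 0.07 over 18 pairs of libraries with the same number (from -0.07 to 0.15). Over 36 pairs with different numbers the median was -0.03 (from -0.19 to 0.16). Deviations within a group add up to 0, which pushes this second median to the opposite sign of the first. It is therefore no separate baseline for an effect of the screen. A fit with the screen number as a block was run as an alternative. Other alternatives were DESeq2 1.42.0, limma on mean log2 values, scaling on control guides, other filters, other null guides, other pseudocounts, and leaving out each library in turn. Both in vitro tests were tested on simulated counts with 200 changed genes. At a log2 change of 2 in either direction, the guide-set test recovered 100% of the changed genes for reactivated against quiescent cells, where 10 unchanged genes of 22849 were also called, and the summed-count test recovered 92% of those lowered and 66% of those raised. For the same comparison in old cells alone the guide-set test recovered 60% of the genes lowered by 2 and 92% of those raised by 2, and the summed-count test recovered 0. Simulated control guides and guides of unchanged genes had the same expected change. In the data for reactivated against quiescent cells, median changes were 0.695 (non-targeting), 0.362 (safe-targeting) and 0.094 (all targeting guides). The number of unchanged genes called in the simulation therefore does not carry over to the data. No library was simulated as thinner than the others of its group, as old reactivated replicate 3 is (TMM factor 0.042 on summed counts). The recovered shares need not hold for the data either, so 0 summed-count calls there do not exclude changes of these sizes. The in vivo permutation test gave a p under 0.05 for 5.7% of 300 simulated genes with no change and for 55.3% at a log2 change of 5. Its simulated gene and control guides had the same spread and no floor at low counts. In the data the median start count of gene guides was 1.28 to 7.13 times that of control guides. These shares therefore do not carry over to the data. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.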

Results

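Neural stem cells from young and old mice were made quiescent in medium with the growth factor BMP4, infected with a genome-wide guide library and then returned to growth medium, and guides were counted in quiescent cells, in cells positive for the division marker Ki67 at day 4 and in reactivated cells at day 14. The libraries comprised 1 of the guide library itself, 2 of young and 1 of old quiescent cells, and 3 each of young and old Ki67-positive and of young and old reactivated cells. In vivo, 25 libraries came from old mice that had received virus with 1 of 5 small guide sublibraries in the lateral ventricle. They hold the olfactory bulb, where newborn neurons arrive, the subventricular zone, where neural stem cells reside, and, for the Top10 sublibrary, cerebellum and cortex. Total counts ran from 8974687 to 42438223 in culture and from 209171 to 2489444 in vivo.

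Guide diversity differed strongly between groups. Quiescent cells held 234362 to 240533 of the 242113 guides at 10 or more counts, close to the 233874 of the guide library. Reactivated young cells held 235887, 128792 and 177190 such guides, and reactivated old cells 95812, 89612 and 18105. In old reactivated replicate 3 the top 1% of guides took 52.54% of the counts (95% Wilson interval 52.52 to 52.55) and the Gini coefficient was 0.969, against 0.305 to 0.377 in quiescent cells. Among Ki67-positive cells, young replicate 1 stood apart with 61758 such guides, against 179413 to 221827 in the other 5 libraries. Counts per guide correlated at r = 0.87 between the quiescent young libraries, at 0.38 to 0.41 between reactivated young and at 0.15 to 0.19 between reactivated old libraries (across guides, which are not independent replicates). No test across groups was made for diversity.

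**Figure D1:**
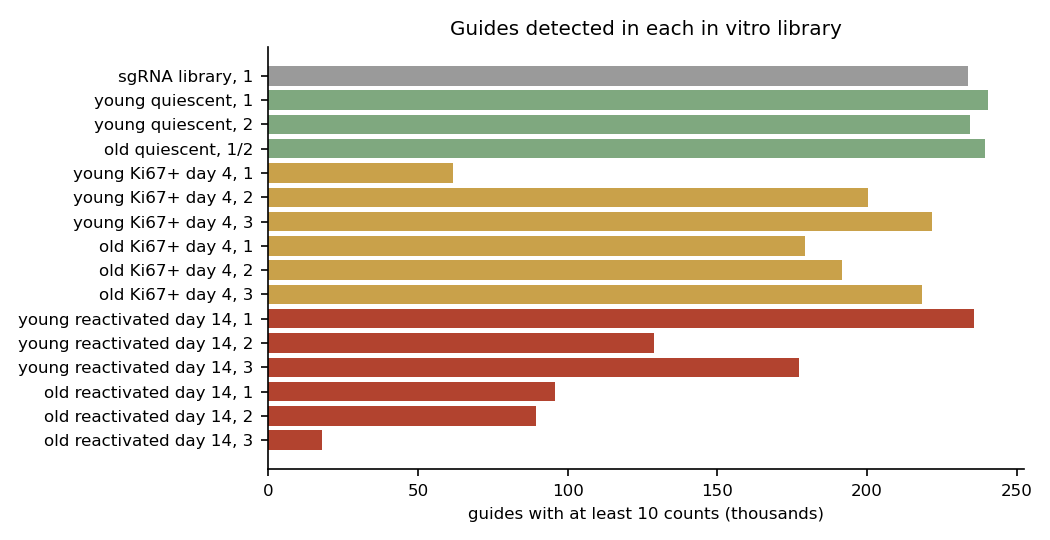
Number of guides with at least 10 counts in each of the 16 libraries from culture; each bar is a library. The 3 old reactivated libraries hold 95812, 89612 and 18105 guides, fewer than the quiescent libraries.

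The comparison of reactivated with quiescent cells asks which gene losses favour or hinder the exit from quiescence and the growth that follows. Guides against Trp53, the p53 tumour suppressor, rose furthest of the named genes, by a median log2 change of 8.51 ± 2.52 (SD, 10 guides) relative to control guides, in 6 of 6 reactivated libraries. Their share of all counts went from 0.0102% ± 0.00173 (SD, n = 2) in young quiescent cells to 1.45% ± 1.08 (SD, n = 3) in young reactivated cells, and from 0.00987% in the old quiescent library to 2.39% ± 2.72 (SD, n = 3) in old reactivated cells. Guides against some genes of BMP signalling, the pathway of the factor that holds these cells quiescent, rose too. Smad4, the shared effector of BMP and TGF-beta receptors, rose by 4.71 ± 1.35, the BMP receptor Bmpr1a by 2.34 ± 1.08 and the BMP co-receptor Rgma by 2.75 ± 1.58, each in 6 of 6 libraries. Lrig1, a membrane protein that restrains growth factor receptors, rose by 3.95 ± 1.37, and the histone acetyltransferase gene Crebbp by 2.72 ± 2.25. The cyclin-dependent kinase inhibitor genes Cdkn1a and Cdkn2a rose by 3.02 ± 1.70 and 3.59 ± 3.66, the Hippo pathway gene Nf2 by 2.81 ± 1.94, Ambra1, an adaptor in autophagy and cyclin turnover, by 2.64 ± 1.69 and the splicing regulator Mbnl1 by 2.93 ± 2.24. These changes are relative to control guides. In old reactivated replicate 3, with a median of 3 counts per guide, the guides of Lrig1 held 0.000155% of all counts, those of Bmpr1a 0.000403%, of Cdkn1a 0.000431% and of Ambra1 0.000127%, against 0.00389%, 0.00356%, 0.00423% and 0.00365% in old quiescent cells. Each gene named in this paragraph kept an adjusted p under 0.05 without any 1 library that could be left out (the old quiescent group has 1).

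By list, 3 of 18 genes of BMP and SMAD signalling were called higher (Smad4, Bmpr1a and Smad1) and 1 lower (Ctdnep1, a phosphatase that acts against BMP signalling), with the same 3 and 1 adjusted over the list alone. Of 20 genes of p53 and cyclin-dependent kinase inhibition, 5 were called higher (Trp53, Cdkn1a, Cdkn2a, Cdkn1b and Bbc3, the last named after its value was seen) and 1 lower (Fbxw7, a ubiquitin ligase subunit), and the same numbers hold adjusted over the list alone. Single higher calls came from the inhibitors of RAS and MAPK (Cbl, 1.55 ± 2.27, 1 of 15) and from the Hippo list (Nf2, 1 of 18). Of 23 Notch genes, Adam10 and Hes1 were called higher and Jag1 lower, and no member of the 62 of the primary cilium list was called (young and old averaged). Without old reactivated replicate 2, the calls of Smad1 (adjusted p = 0.704), Cdkn1b (0.861), Cbl (0.217), Adam10 (0.278), Hes1 (0.658), Fbxw7 (0.152) and Ctdnep1 (0.244) were lost. Without young reactivated replicate 3 those of Smad1 (0.0564), Adam10 (0.058), Fbxw7 (0.0566) and Ctdnep1 (0.0534) were. Old reactivated replicate 3 ended the calls of Cdkn1b (0.0675), Cbl (0.323), Adam10 (0.116) and Fbxw7 (0.0528) when left out, and young reactivated replicate 2 those of Cdkn1b (0.18), Adam10 (0.062) and Fbxw7 (0.0522). Young quiescent replicate 1 did so for Smad1 (0.0612) and Cbl (0.0621), and young quiescent replicate 2 for Adam10 (0.0643). With the screen number as a block, the calls of Cdkn1b (adjusted p = 0.16) and Cbl (0.0996) were lost.

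Guides against the machinery that dividing cells need fell. Of 75 genes of the cytosolic ribosome 70 were called lower, among them Rps29 (-2.81 ± 1.00) and Rps12 (-2.72 ± 1.10), and 72 adjusted over the list alone. So were 30 of 31 proteasome genes (Psmb1, -2.45 ± 0.70), 32 of 34 spliceosome genes (Snrpb, -2.56 ± 1.06), 37 of 42 DNA replication genes (Pcna, -2.52 ± 1.11), 34 of 39 mitosis genes, 18 of 20 RNA polymerase genes, 19 of 20 tRNA synthetases (Cars, -2.37 ± 0.67) and 52 of 73 genes of the mitochondrial ribosome. Adjusted over each list alone, these counts were 31, 33, 41, 37, 20, 20 and 63. In the respiratory chain 31 of 61 genes were lower (48 adjusted over the list alone), with Uqcrc2 at -2.66 ± 1.44 and Cyc1 at -2.08 ± 0.65. Sod1, which removes superoxide (-2.57 ± 1.27), and the RNA polymerase III factor gene Gtf3c1 (-2.65 ± 1.53) fell as well. No gene of these lists was called higher over all genes, and 1 of the cytosolic ribosome was higher adjusted over the list alone.

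Some genes of growth factor signalling and lineage fell as well, in lists that as wholes did not pass (below); over all genes 2722 of 22849 were called lower. Of 28 cell cycle drivers 6 were lower (Ccnd1, the cyclin D1 gene, -2.02 ± 1.21, and Cdk4, -2.14 ± 1.22) and E2f1 higher (1.29 ± 0.87), against 8 and 1 adjusted over the list alone. Of EGF, FGF, RAS and MAPK signalling 7 of 22 promoting genes were lower (Ptpn11, -2.29 ± 1.47, and Fgfr1, -1.93 ± 0.75; 9 adjusted over the list alone). Of 26 genes that promote insulin, PI3K and mTOR signalling 6 were lower (Pdpk1, -1.85 ± 0.56; 10 adjusted over the list alone), and of 26 of cholesterol synthesis 11 (Hmgcs1, -1.91 ± 1.36; 14 adjusted over the list alone). Among 30 neural stem cell regulators 6 were lower and 2 higher (Lrig1 and Hes1), with 8 and 2 adjusted over the list alone. The lower ones include the transcription factor genes Olig2 (-2.14 ± 0.52) and Sox2 (-1.39 ± 1.34). The call of Sox2 was lost without old reactivated replicate 3 (adjusted p = 0.0687). The call of Hes1 was lost without old reactivated replicate 1 (adjusted p = 0.0521) or 2 (0.658) or young reactivated replicate 2 (0.0716). That of E2f1 was lost without old reactivated replicate 2 (0.303) or 3 (0.223), either young quiescent replicate (0.208 and 0.059) or young reactivated replicate 2 (0.0522) or 3 (0.193). Without old reactivated replicate 2 Eno1 (0.237) and Atxn2l (0.102) were lost too, and Atxn2l without replicate 3 (0.119). A fit with the screen number as a block lost E2f1 (adjusted p = 0.295), Eno1 (0.0941) and Ybx1 (0.134). Lysosome and autophagy genes were lower for 8 of 42 (9 adjusted over the list alone; Atp6v0d1, a proton pump subunit, -2.25 ± 0.67), ribonucleoprotein granule genes for 4 of 38 (Atxn2l, Cnot1, Pabpc1 and Ybx1; 4 adjusted over the list alone) and glycolysis genes for 3 of 27 (Eno1, Gapdh and Pgam1; 4 adjusted over the list alone). No glucose transporter of 14 was called with young and old averaged. Slc2a4, which encodes the insulin-responsive transporter GLUT4, gave -0.30 ± 1.81 with an adjusted p of 0.996.

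**Figure D2:**
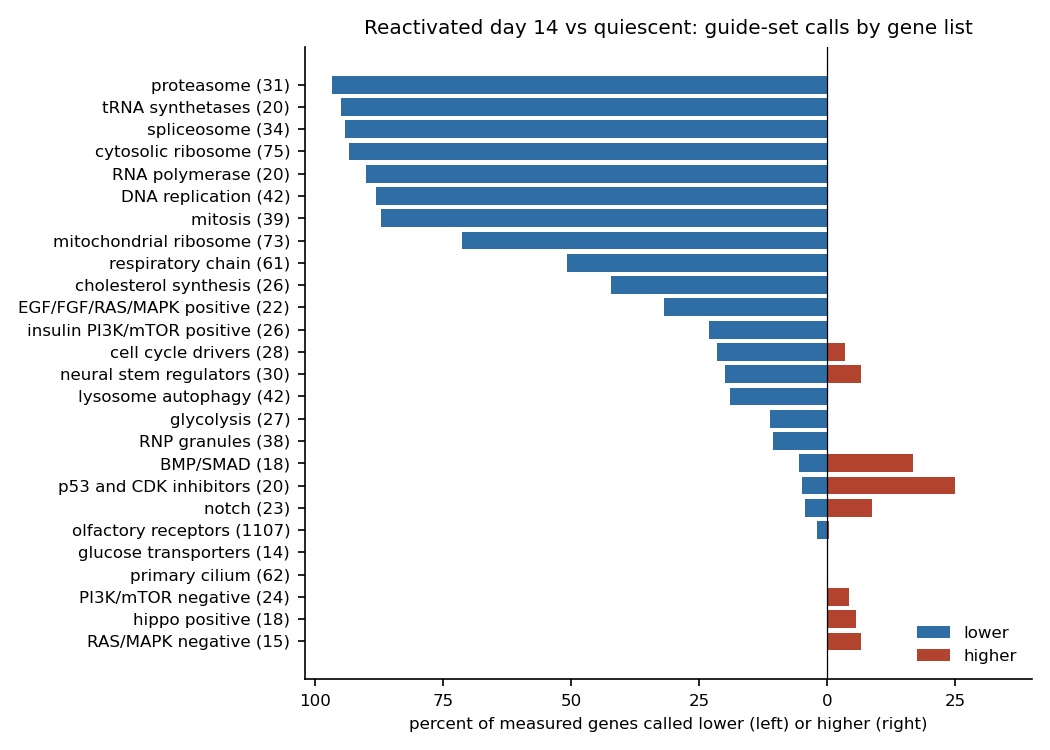
Percent of the measured genes of each of 26 gene lists called lower or higher in reactivated against quiescent cells, young and old averaged; the number of genes is in brackets. In the cytosolic ribosome list 70 of 75 genes are called lower, and in the list of p53 and cyclin-dependent kinase inhibitors 5 of 20 are called higher.

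In all, the guide-set test called 61 genes higher and 2722 lower. Smad4 (chromosome 18, 73634790 to 73703791 in GRCm38.p6, ENSMUSG00000024515), Lrig1 (chromosome 6, 94604529 to 94700298, ENSMUSG00000030029), Trp53 (chromosome 11, 69580348 to 69591873), Rps29 (chromosome 12, 69157722 to 69159186) and Sod1 (chromosome 16, 90220762 to 90226333) each had an adjusted p of 0.000112, the smallest the draws allowed here. The summed-count test of edgeR called 0 genes, with 534 higher and 702 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.427. On the same sums DESeq2 called 1068 (1064 higher), limma 0, and edgeR scaled on control guides 207 (all lower). For Smad4 the summed log2 change was 5.39 ± 1.80 (SE) and for Trp53 9.01 ± 3.38. Random draws from all guides in place of control guides gave 163 genes higher and 929 lower, and without old reactivated replicate 2 the control-guide draws gave 41 higher and 1361 lower. Some of the named genes with lower guides share guides with other genes: 9 of the 10 guides of the histone gene Hist1h2ao (-2.64 ± 1.29) are also counted under other genes, and 4 of those of Rps12.

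Tested as lists, 7 shifted up and 7 down in reactivated cells by fry. Those down were the cytosolic ribosome, proteasome, spliceosome and RNA polymerases (each adjusted p = 0.0285) and DNA replication, tRNA synthetases and the respiratory chain (each 0.0315), and each also passed in camera with an estimated correlation (adjusted p = 0.0478). The mitochondrial ribosome (0.0547), mitosis (0.0527), cholesterol synthesis (0.0527) and the promoters of insulin, PI3K and mTOR signalling (0.0621) did not pass. Lists shifted up were p53 and cyclin-dependent kinase inhibitors and the Hippo list (each 0.0285, and 0.0478 with an estimated correlation), BMP and SMAD signalling (0.0285; adjusted p = 0.0575 with an estimated correlation), and the inhibitors of RAS and MAPK (0.0285) and of PI3K and mTOR (0.0323) and the primary cilium (0.0315), for which the adjusted p was 0.0721 with an estimated correlation. Olfactory receptor genes, with 3 of 1107 called higher and 21 lower and 0 adjusted over the list alone, also shifted up (0.0473; adjusted p = 0.127 with an estimated correlation). For the Notch list (0.21), neural stem cell regulators (0.532), ribonucleoprotein granules (0.149), lysosome and autophagy (0.704), glycolysis (0.995), glucose transporters (0.346), EGF and MAPK promoters (0.257) and cell cycle drivers (0.346) fry did not pass. In the lysosome list the median log2 change relative to all genes was -0.24 and the mean 0.08, and for glycolysis fry pointed up while the median was -0.28. With the screen number as a block 5 lists shifted up and 5 down: DNA replication (adjusted p = 0.0501), the respiratory chain (0.0546), the primary cilium (0.083) and olfactory receptors (0.167) were lost. Camera with an estimated correlation passed 9 lists without and 0 with the block. With the highest guide of each gene and library left out, 0 lists shifted up and 8 down.

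In old cells alone, the comparison of reactivated with quiescent cells gave fewer calls, led as in the averaged comparison by Trp53, Smad4 and Lrig1. The averaged comparison includes these old libraries. Crebbp, Mbnl1 and Cdkn2a, called higher there, were not called in old cells. Guides against Trp53 rose by 9.73 ± 2.01 (SD, 10 guides), Smad4 by 5.36 ± 1.87 and Lrig1 by 4.89 ± 1.94, each in 3 of 3 libraries relative to control guides (each adjusted p = 0.0114, guide-set test on edgeR scores). As a share of counts, Lrig1 fell in replicate 3 (0.000155% against 0.00389% in quiescent cells). Bmpr1a (2.74), Rgma (2.68 ± 2.26), Cdkn1a (2.94 ± 1.88), Ambra1 (2.98 ± 2.21), Nf2 (3.46 ± 3.69) and the glucocorticoid receptor gene Nr3c1 (2.79 ± 4.10) made up the 9 higher calls. Guides against the nuclear transport gene Rangap1 (-3.72 ± 2.75), Rps29 (-3.01 ± 2.29) and Sod1 (-2.99 ± 1.98) fell, among 103 lower calls. By list, 5 of 75 genes of the cytosolic ribosome, 3 of 31 of the proteasome and 3 of 42 of DNA replication (Pcna, Rrm1 and Top2a) were lower, against 44, 15 and 23 adjusted over the list alone. In the spliceosome and mitosis lists 0 were called, against 23 and 22 adjusted over the list alone. No list shifted by fry (adjusted p from 0.203 to 0.973), while camera with its preset correlation passed 15 and with an estimated correlation 0. The call count fell to 1 without old reactivated replicate 2 (Smad4 alone stayed; Trp53 and Lrig1 had adjusted p = 0.16) and to 21 without replicate 1, where Cdkn1a (0.102), Bmpr1a (0.102), Rgma (0.0866), Ambra1 (0.121), Nf2 (0.117), Nr3c1 (0.0679), Pcna (0.0853), Rrm1 (0.0902) and Top2a (0.115) were among the calls lost. Without replicate 3 it was 249, and Nf2 (0.0745), Nr3c1 (0.14), Pcna (0.0531) and Rrm1 (0.0869) were lost. With the screen number as a block it was 3 (Trp53, Smad4 and Lrig1), and the other genes named here had an adjusted p from 0.0914 (Cdkn1a and Rgma) to 0.234 (Pcna). Draws from all guides gave 20 higher and 12 lower, draws from safe-targeting guides 5 higher and 21 lower. The summed-count test of edgeR called 0 genes (433 higher and 132 lower at an unadjusted p under 0.05; DESeq2 1525, limma 0, edgeR scaled on control guides 57). Leaving out the single old quiescent library is impossible.

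In young cells alone, guides against Trp53 rose by 7.44 ± 3.18, Crebbp by 4.51 ± 1.72, Lrig1 by 3.78 ± 1.19 and Smad4 by 3.77 ± 1.39 (SD, 10 guides), each in 3 of 3 libraries. Tfg (1.83 ± 1.02), Rgma (2.08 ± 1.45), Bmpr1a (1.49 ± 0.96), Cdkn2a (3.85 ± 3.74) and Cdkn1a (2.08 ± 2.31) rose too, among 48 higher calls. Lower calls numbered 3657 and included Rps12 (-3.18 ± 0.34), Rps3 (-2.82 ± 0.56), Sox2 (-2.12 ± 0.45), Olig2 (-2.28 ± 0.50), the EGF receptor gene Egfr (-1.99 ± 1.79) and Rictor, of the mTOR complex (-2.01). Of 23 Notch genes Mib1 (-1.71 ± 0.83), Jag1 (-1.33 ± 1.44) and Psenen (-1.53 ± 0.90) were lower and 0 higher, and Ift27 of the primary cilium list (-1.36 ± 0.87) and the glucose transporter gene Slc2a3 (-1.22 ± 1.55, adjusted p = 0.0448) were lower. These calls were lost without young reactivated replicate 1 (Psenen 0.0509, Slc2a3 0.34), 2 (Ift27 0.071, Jag1 0.0582, Psenen 0.206, Slc2a3 0.133) or 3 (Mib1 0.0994) or young quiescent replicate 2 (Psenen 0.105, Slc2a3 0.08). Most genes of the 10 machinery lists were called lower, 372 of 421, and 312 of 334 without the respiratory chain and cholesterol synthesis. Among them were 72 of 75 cytosolic ribosome, 31 of 31 proteasome, 40 of 42 DNA replication, 38 of 39 mitosis, 20 of 20 tRNA synthetase and 60 of 73 mitochondrial ribosome genes, with 73, 31, 42, 38, 20 and 68 adjusted over the list alone. By fry no list passed by direction (smallest adjusted p = 0.0804) and 1, the RNA polymerases, passed its mixed test (0.0492; 0 lists with the screen number as a block), and camera passed 20 with its preset and 12 with an estimated correlation, the latter 0 with the screen number as a block. Calls numbered 2367 without young reactivated replicate 3, and draws from all guides gave 171 higher and 1335 lower. The summed-count test of edgeR called 0 genes (215 higher and 276 lower at an unadjusted p under 0.05; DESeq2 5, limma 1, edgeR scaled on control guides 0). Of 9 genes higher in old cells 8 were also higher in young cells, and of 103 lower ones 92 were also lower (0.0189 and 16.5 expected for independent lists; Fisher's exact test p = 1.84e-21 and 7.34e-61, across genes). No library is shared between these comparisons, but both use 1 fit, the same guides and the same control guides. The lists can therefore overlap without a replicated gene effect, and these p-values do not measure replication.

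**Figure D3:**
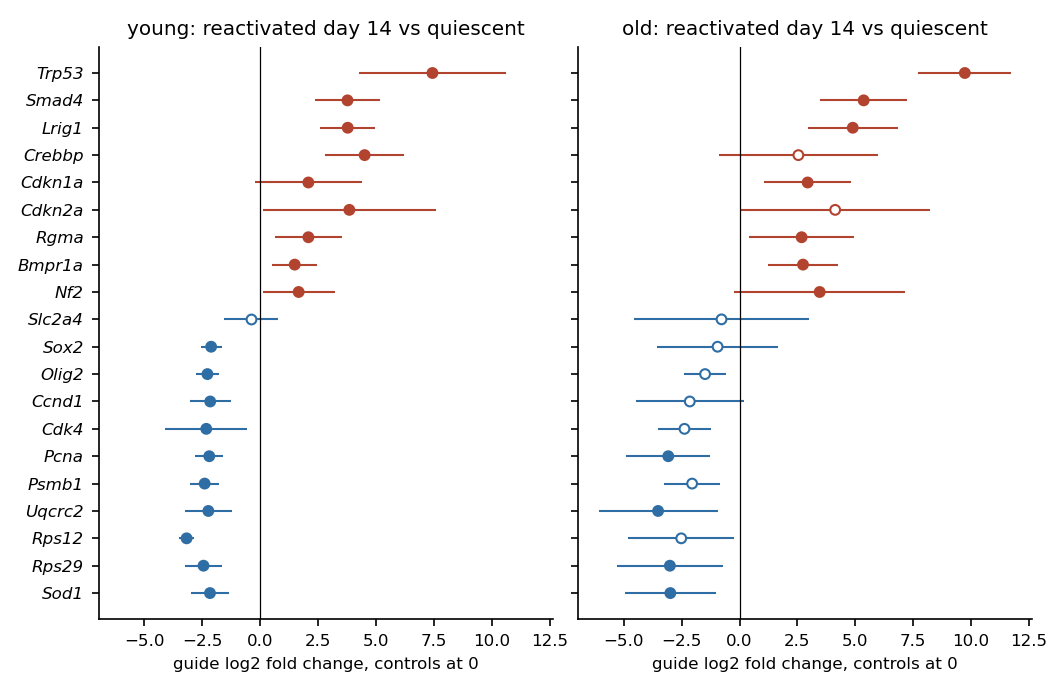
Median log2 change over guides relative to control guides, with the SD over guides, of 20 genes in young and in old reactivated against quiescent cells; filled points have an adjusted p under 0.05, red points lie above and blue points below the control guides. Trp53 is highest in both panels, at 7.44 in young and 9.73 in old cells.

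Between old and young cells the guide-set test called no gene, while the tests on summed counts ranged widely. No changes between ages were simulated, so a count of 0 does not measure how small a difference between ages is. In reactivated cells, the guide-set test called 0 genes (594 higher in old and 360 lower at an unadjusted p under 0.05) and so it did in Ki67-positive cells (632 and 725). Slc2a4 gave 0.05 ± 3.90 in old against young reactivated cells (adjusted p = 0.999) and -0.52 ± 1.93 in Ki67-positive cells (0.983). Its summed log2 change in old against young reactivated cells was 5.15 ± 1.76 (SE, edgeR adjusted p = 0.0563). The summed-count test of edgeR called 0 genes for reactivated cells, with 6214 higher in old and 1264 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.0561. DESeq2 called 2993, limma 0 and edgeR scaled on control guides 17 (1 higher, 16 lower). These counts depend on single old libraries: without old reactivated replicate 1, 2 or 3, edgeR called 6249, 5460 or 944 genes. The cause was not tested. For Ki67-positive cells edgeR called 0 on the sums (6 higher and 14 lower at an unadjusted p under 0.05), DESeq2 0 and limma 0, and the guide-set test called 10 without old Ki67-positive replicate 1. The guide-set test of reactivated cells called 1 without young reactivated replicate 2. None of the 26 gene lists shifted (smallest fry adjusted p 0.143 in reactivated and 0.986 in Ki67-positive cells), and the changes of each age from its own quiescent cells differed for 0 genes in both tests.

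Few genes were called between Ki67-positive cells at day 4, soon after the return to growth medium, and quiescent cells. With young and old averaged, the guide-set test gave 430 genes higher and 1420 lower at an unadjusted p under 0.05. A fit of only the compared libraries, in 2 groups, called 181 genes against 5 in the fit of all libraries. Recovery of known changes was not simulated for this comparison, so a low count does not measure how small the difference is. Guides against the ribosomal genes Rpl37 (-1.43 ± 1.74) and Rpl30 (-1.41 ± 1.64), the chaperonin gene Cct2 (-1.41 ± 1.72), Brap (-1.14 ± 2.20) and Gm11032 (-1.80 ± 1.69) fell with young and old averaged, each with an adjusted p of 0.0457. These were the 5 calls, lower in 6 of 6 libraries for Rpl37, Cct2, Brap and Rpl30 and in 5 of 6 for Gm11032. Within the cytosolic ribosome list 2 of 75 genes were called, and 43 adjusted over the list alone. In old cells only St6galnac2, a sialyltransferase gene (chromosome 11, 116676703 to 116695782), rose, by 1.26 ± 1.28 with 9 of 10 guides and 3 of 3 libraries higher (adjusted p = 0.0457). Its call was lost without old Ki67-positive replicate 1 (0.245), 2 (0.24) or 3 (0.249) and with the screen number as a block, where the count was 0. In young cells the guide-set test called 0 genes, with 476 higher and 1197 lower at an unadjusted p under 0.05. No list shifted by fry in any of these comparisons; for young and old averaged, 7 lists, the ribosome list among them, passed in camera with its preset correlation (3 with the screen number as a block) and 0 with an estimated correlation (smallest adjusted p = 0.251). A single gene was called, higher, in the fit with the screen number as a block. Counts were 38 without old Ki67-positive replicate 1, 28 without young Ki67-positive replicate 1 and 13 without young quiescent replicate 2. They were 1 without old Ki67-positive replicate 3 and 0 without old replicate 2 or young replicate 3. Calls of Brap (0.144), Cct2 (0.19), Gm11032 (0.228) and Rpl30 (0.144) were lost without young replicate 2. In young cells alone they were 13 without replicate 1 and 1 without replicate 2. The summed-count tests of edgeR, DESeq2 and limma called 0 genes (0 in the averaged comparison at an unadjusted p under 0.05, 0 in old and 1 in young cells).

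Reactivated against Ki67-positive cells sets day 14 against day 4, where time and the selection for Ki67 change together. Guides against Trp53 rose by 6.93 ± 1.97 in 6 of 6 libraries, Smad4 by 3.73 ± 1.51 and Lrig1 by 3.40 ± 1.15 in 5 of 6, and Rgma (2.78 ± 1.42), Mbnl1 (2.66 ± 2.27), Crebbp (2.47 ± 2.11) and Cdkn2a (4.00 ± 3.02) rose as well. The chromatin remodelling gene Arid1a (1.90 ± 1.16), Tfg (2.02 ± 0.90) and Nf2 (3.13) were also higher. Guides against the spliceosome genes Snrpb2 (-3.21 ± 1.77) and Lsm4 (-2.68), the proteasome gene Psmc5 (-2.56), the nuclear pore gene Nup205 (-2.41) and Sod1 (-2.94 ± 1.24) fell. The guide-set test called 39 genes higher and 1248 lower (smallest adjusted p 0.00138), against 39 and 116 with draws from all guides and 44 and 614 with safe-targeting guides. Tfg was lost without old reactivated replicate 1 (adjusted p = 0.119) and Arid1a without old reactivated replicate 2 (0.0507). Counts moved to 769 without old Ki67-positive replicate 1, 199 without old reactivated replicate 2, 778 and 712 without young Ki67-positive replicates 2 and 3, and 2462, 659 and 446 without young reactivated replicates 1, 2 and 3. The summed-count test of edgeR called 0 genes (5617 higher and 1068 lower at an unadjusted p under 0.05; DESeq2 2173, limma 37, edgeR scaled on control guides 417). On those sums edgeR called 5061 without old reactivated replicate 1, 4420 without replicate 2, 1 without replicate 3 and 91 without young reactivated replicate 1.

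Quiescent cells against the guide library test for losses during infection and quiescence. The guide-set test called 3051 genes higher and 4241 lower, led by the transporter gene Slc22a2 (2.02 ± 0.72) and Lrrc61 (1.84 ± 0.80) among the higher and by Mad2l2, a DNA repair gene (-1.54 ± 0.31), and Polr2f, a subunit of RNA polymerases (-1.56 ± 0.16), among the lower, each in 3 of 3 libraries. These calls followed the cloning pools: with scores centred within each of the 20 pools, 143 genes were higher and 86 lower. The summed-count test of edgeR called 0 genes (35 higher and 0 lower at an unadjusted p under 0.05; DESeq2 0, limma 0). With only the compared groups in the fit it called 9670 (4960 higher, 4710 lower). The guide library, a single replicate, cannot be left out.

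In the olfactory bulb, 28 of the 50 sublibrary genes had guides above the control guides and 2 below, relative to the subventricular zone at 24 h. Set against the guides of the other genes in the same sublibrary in place of control guides, 0 of the 28 stayed called. The bulb labels give no collection time, so tissue and time after infection are not separated here. Many control guides were nearly absent from the bulb. Those with 10 or more counts were 17.5% for the published regulators, 31.0% for glucose and 38.0% for ribonucleoprotein. They were 40.5% for Depleted and 56.0% for Top10. Rises and falls below are relative to these control guides. A gene guide that merely stayed detected can therefore score as a large rise, and the sizes are not gains in abundance. These comparisons ask whether the loss of a gene changes how many descendants of infected cells reach the bulb of old mice. In the Top10 sublibrary 7 genes rose, from RASSF8 (median log2 difference 6.23 ± 2.44, SD over guides) and NPB, a neuropeptide gene (6.34 ± 2.31), to SPP1, which encodes osteopontin (6.44 ± 2.85), RSPH3A, a radial spoke gene (6.60 ± 1.63), and PXDC1 (6.98 ± 2.64), with LRMDA (6.44 ± 0.72) and CCDC15 (6.58 ± 2.01) between. Adjusted permutation p ran from 0.001 (RSPH3A) to 0.0196 (RASSF8), and B3GALNT2 (1.83, 0.0816), FAM53C (1.56) and AA986860 (3.51, 0.278) did not pass. By screen the differences were uneven, 1.95 in screen 1 and 11.92 in screen 2 for PXDC1. RASSF8 was lost without bulb replicate 1 (adjusted permutation p = 0.0842), and without bulb replicate 2 B3GALNT2 (0.0005) and FAM53C (0.00169) passed.

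Among the genes of the glucose and human disease sublibrary, SLC2A4 rose by 6.04 ± 0.78 (5 guides, adjusted permutation p = 0.0264). By screen its differences were 8.64 in screen 1 and 3.62 in screen 2. C1QTNF5 rose by 7.46 ± 0.25 (3 guides, adjusted permutation p = 0.0253). SLC2A12, another glucose transporter gene, fell by 2.59 ± 0.88 relative to control guides (4 guides, adjusted permutation p = 0.001). Its differences were -2.32 in screen 1 and -2.46 in screen 2. Its mean start count, 3815, was the lowest of the sublibrary (others 8371 to 31113). Guides in these bulbs had median counts of 2 and 5, near the floor. How far low counts set this fall was not tested. SLIT2 (6.31, 0.111), IER2 (6.18, 0.0501), SORL1 (6.30, 0.242), SLC45A4 (4.27) and SNRPB2 (1.76) did not pass. Without bulb replicate 1 the adjusted permutation p was 0.622 for SLC2A4 and 0.182 for C1QTNF5, leaving 1 call (SLC2A12); without bulb replicate 2 there were 7, SLIT2 (0.00669) and SLC45A4 (0.0374) among them. For SLC2A4 the value was also 0.0642 with a pseudocount of 10, 0.946 with counts summed over guides and 0.835 against the guides of the other genes; for C1QTNF5 these were 0.0594, 0.697 and 0.689. In the Depleted sublibrary 1 gene, DBPHT2, fell by 5.91 ± 0.63 (2 guides, 0.0187); the ribosomal genes RPLP1 (-5.70 ± 3.81, 0.0754) and RPL32 (0.96 ± 6.53, 0.338) did not pass. DBPHT2 was lost without bulb replicate 1 (adjusted permutation p = 0.108, 0 calls), and without bulb replicate 2 there were 7 lower calls, RPLP1 (0.0004) and ZFP541 (0.0004) among them.

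For genes of cytoplasmic ribonucleoprotein structures 9 of 10 rose, with the translation initiation factor gene EIF4E (10.51 ± 1.28), MBNL1 (10.55 ± 1.93), the splicing regulator RBM4 (10.04 ± 0.46) and SOCS1, an inhibitor of cytokine signalling (9.54 ± 0.71), each at an adjusted permutation p of 0.001. EDC3 (9.92), RBPMS (9.45), PAPPA2 (9.16), DIS3L2 (9.03) and GRB7 (8.89) rose as well, and CNOT3 gave 2.98 ± 5.23 (0.626). The reference libraries differ: control guides hold 71.47% of the counts in subventricular zone replicate 2, whose label code has another form, against 26.25% in replicate 1 and 25.65% and 26.86% in the bulbs. EIF4E, RBM4 and SOCS1 stayed called without any 1 library; the others were lost at least once. Without bulb replicate 1 there were 4 calls (lost: DIS3L2 at 0.149, EDC3 and MBNL1 at 0.0527, GRB7 at 0.345 and RBPMS at 0.195), without bulb replicate 2 there were 5 (DIS3L2 0.0739, EDC3 0.22, PAPPA2 0.14 and RBPMS 0.0751) and without subventricular zone replicate 2 there were 5 (DIS3L2 0.101, EDC3 0.0538, GRB7 0.158 and RBPMS 0.0662). All 10 published regulators rose, among them Olig2 (7.65 ± 2.30), Bmpr2 (7.23 ± 6.43), Sox2 (7.16 ± 5.43), Hes1 (7.06), Igf1r (6.64), Bmpr1a (6.44 ± 1.33), Cdkn1a (5.93 ± 1.73), the astrocyte and stem cell filament gene Gfap (5.72) and Id4 (5.48), with adjusted permutation p from 0.0048 to 0.0219. In culture Olig2 and Sox2 guides were lower than control guides in reactivated cells, while Bmpr1a and Cdkn1a guides were higher; the difference between the settings was not tested. By screen most were far apart, 2.76 and 12.22 for Olig2, 1.82 and 12.20 for Sox2, 1.44 and 12.66 for Hes1 and 0.35 and 10.61 for Id4, while Bmpr2 gave 2.44 and 2.99, each below its value over both screens. Control guides hold 84.05% of the counts in their subventricular zone replicate 1 and 21.55% in replicate 2. There were 9 calls without bulb replicate 1 (Bmpr2 at 0.338) and 2 without bulb replicate 2, and without subventricular zone replicate 1 only Olig2 stayed.

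**Figure D4:**
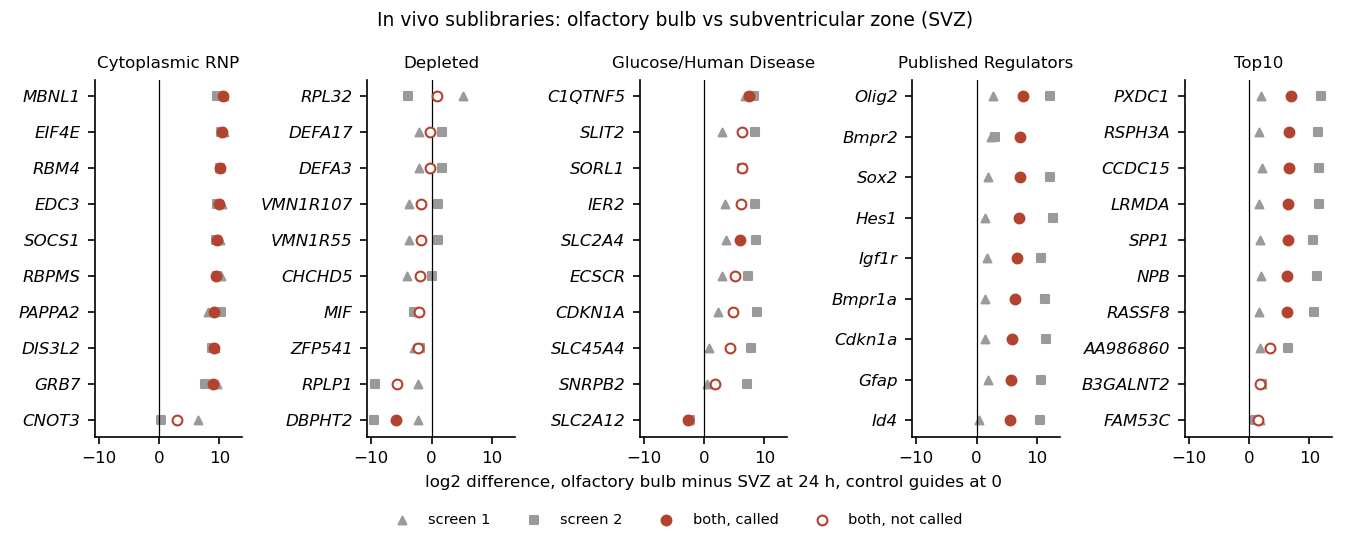
Median log2 difference between olfactory bulb and subventricular zone at 24 h, relative to control guides, for genes of each of 5 sublibraries. Triangles show screen 1 and squares screen 2, except in the glucose panel, where triangles show screen 2 and squares screen 1. Circles show both screens, filled where the adjusted permutation p is under 0.05. SLC2A4 sits at 6.04 and SLC2A12 at -2.59.

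Between Top10 bulbs of the other mice and of mice labelled WT, all 10 genes were higher in the other mice, from 5.06 for B3GALNT2 (adjusted permutation p = 0.00075) to 11.25 for CCDC15 (0.0004). Without bulb replicate 1 of the other mice FAM53C was lost (0.119), and without replicate 1 of the WT mice AA986860 (0.0548). Against the guides of the other genes 0 of the 10 stayed called, with CCDC15 at -0.58 and B3GALNT2 at -1.79, and a minimum of 50 counts in the reference left 0 calls. Mean counts of the genes in the WT bulbs were 1 to 17, so the size of these differences rests on a nearly empty reference. In WT replicate 2, 1 control guide took 99.54% of the counts (95% Wilson interval 99.52 to 99.55), and in replicate 1 the highest guide, also a control, took 67.21% (67.04 to 67.37). There, 30 and 74 guides reached 10 counts, against 130 and 62 in replicates 1 and 2 of the other mice.

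Tested guide by guide with edgeR, most guides called in the Depleted, glucose and ribonucleoprotein sublibraries were control guides. Control guides are 100 of the 145, 143 and 147 guides there. For Top10, Depleted and glucose the subventricular zone reference is 1 library, so the spread comes from the 2 bulb libraries alone. Of 146 Top10 guides 0 were called (6 at an unadjusted p under 0.05; DESeq2 31), and of the published regulators 0 (0 at an unadjusted p under 0.05; DESeq2 65, and with edgeR 45 without subventricular zone replicate 1 and 1 without replicate 2). In the Depleted, glucose and ribonucleoprotein sublibraries 32, 48 and 25 guides were called lower, of which 23, 43 and 23 were control guides; with TMM scaling 0, 38 and 0 were called. In the WT comparison 51 guides were higher and 9 lower, 17 of them controls, against 5 with TMM scaling and 123 without bulb replicate 2 of the other mice. With the screen number as a block the ribonucleoprotein and WT counts were 11 and 25. Without a library the ribonucleoprotein count was 67 or 78 (bulb replicate 1 or 2) and 8 (subventricular zone replicate 2), and the WT count was 33 without bulb replicate 1 of the other mice.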

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

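The tests with safe-targeting guides, of core gene lists, of cloning pools and against the guides of other genes were chosen only after the results were seen; the splits of the libraries were planned. Single Top10 libraries stand in no comparison of the report, and each holds guides at 10 or more counts. There were 146 such guides in the subventricular zone at 5 weeks, 32 in the olfactory bulb at 24 h, 39 in the cerebellum at 24 h, 31 in the cortex at 24 h, 75 in the cerebellum at 5 weeks and 40 in the cortex at 5 weeks. The top 10 guides took 99.84% to 99.95% of the counts in each of these but the subventricular zone (15.32%). Whether the remaining guides there are more than traces was not tested.

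Guides against 2722 genes were called lower at reactivation by the guide-set test. Non-targeting controls make no break in DNA, and controls that gain for that reason would lower every gene alike; with safe-targeting guides alone as the null 70.6% of the lower calls stayed, which argues against this as the whole cause of the averaged count (in old cells alone 21 of 103 lower calls stayed, and against Ki67-positive cells 614 of 1248). Loss of genes that dividing cells need is the other explanation tested: with draws from all guides, 181 of 421 genes of the 10 machinery lists named in the methods were called lower against 748 of 22428 other genes, a ratio of shares of 12.9 (7.5 with control guides), which is consistent with it for these lists, though they hold only 12.3% of the 2722 calls. Part of the count still depends on the null, since median changes of non-targeting (0.695), safe-targeting (0.362) and olfactory receptor guides (0.302) differed. How far the loss of guides from a library by chance adds to the count stays open and was not tested.

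Calls between quiescent cells and the guide library numbered 7292. Centred within cloning pools, 1.15% of them stayed, and the pool means of control and of targeting guides correlated at r = 0.999 over 20 pools, which is consistent with a different mix of pools in the guide library and in the cells. Control guides target no gene, so gene loss cannot move their pool means. No biological explanation was tested for the calls that stayed.

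In the olfactory bulb 28 genes were higher than control guides. Against the guides of the other genes 0.0% of them stayed called, which is consistent with a difference between gene guides and control guides as classes. At the start, in the subventricular zone at 24 h, gene guides had 7.13 times the median count of control guides in the glucose sublibrary, 6.36 times in that of published regulators, 2.48 times in the ribonucleoprotein sublibrary, 1.92 times in Top10 and 1.28 times in Depleted. Within sublibraries the start count of gene guides correlated with their bulb count at Spearman 0.56 to 0.75 (control guides 0.04 to 0.38), so a part of starting abundance stays open. A rise shared by most genes of a sublibrary would look the same in this test, so the loss of these genes as a biological cause stays open.

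For counts of calls, other splits of the same libraries were tried, with only the compared libraries in the fit. Of 84, 84 and 462 possible splits for the first 3 comparisons 21 each were drawn, the real one included, so 1 of 21 is the smallest share they can give, and they ignore the screen number. By the guide-set test, the real split gave the most calls for reactivated against quiescent cells (3263 genes, at most 1 in the others). There, 1 of 21 splits reached the real count. The real split was also the highest for reactivated against Ki67-positive cells (1529 and 931, 1 of 21). In that comparison leaving out single libraries gave from 199 to 2462 calls. These splits cannot exclude chance, since they can give no smaller share and the libraries are not interchangeable (old reactivated replicate 3, below). For Ki67-positive against quiescent cells the real split was also the highest (181 and 100; 1 of 21). No conclusion is drawn there either, and the count was unstable. The fit of the report gave 5 calls, and with the screen number as a replicate block 1 was left (2029 and 1078 in the other comparisons). Without old replicate 2 or young replicate 3 there were 0. By the summed-count test each real split gave 0 genes, so all of its splits reach that count (21 of 21 each) and nothing about chance follows. The others gave at most 4783, 0 and 0; the 4783 point to a structure of the libraries other than the groups. Each split with 3495 or more such calls puts old reactivated replicate 3 in the other group, and those that keep it in place gave at most 90. Its TMM factor on summed counts was 0.042, against 0.644 to 1.423 in the other libraries. For old against young cells the 10 splits are too few; the real and highest other counts were 0 and 5 (summed, reactivated), 0 and 0 (summed, Ki67-positive), 0 and 2 (guide sets, reactivated) and 0 and 9 (guide sets, Ki67-positive).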

How the results depend on the processing

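Tests with safe-targeting guides alone, pool centring, only the compared groups, other genes' guides in vivo, and without the 2 libraries with the fewest guides at 10 counts (young Ki67-positive replicate 1 and old reactivated replicate 3) were chosen after seeing the data. The cause was not tested for any change below unless stated. Low counts limit what single guides can show in libraries with a median of 1 to 5 counts per guide, in culture and in vivo, also at a high total (35523148 counts in old reactivated replicate 3). Their part was not separated from the spread between libraries. Of named results, 1626 of 1791 kept their side of the threshold and direction for reactivated against quiescent cells (159 weaker, 6 reversed). So did 222 of 374 in old cells (146 weaker, 6 reversed), 1362 of 1456 in young cells (86 and 8) and 1506 of 1740 for reactivated against Ki67-positive cells (232 and 2). The numbers were 69 of 96 for Ki67-positive against quiescent cells (27 weaker), 15 of 22 for the same in old cells (7 weaker) and 373 of 494 in vivo (77 weaker, 12 stronger, 32 reversed). Some settings in these tallies could not change the outcome. In vivo, centring on the median of all guides (52 kept) and the replicate block (29 kept) leave the test unchanged. A minimum of 6 guides per gene left each guide-set p unchanged. It kept 111, 34, 112 and 87 results (reactivated against quiescent averaged, old, young, and against Ki67-positive). The kept shares therefore overstate stability. The old quiescent cells and the guide library have 1 library each and cannot be left out; a lone library left in a group is assumed to vary like the others. In vivo guide fits of Top10, Depleted and glucose have no residual degrees of freedom without a library and gave no value.

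Counts of calls without each library in turn ranged, for summed counts, from 0 to 6249 for old against young reactivated cells, from 0 to 5061 for reactivated against Ki67-positive cells and stayed 0 elsewhere. For guide sets they ranged from 1402 to 3614 (reactivated against quiescent), 1 to 249 (old), 2367 to 3687 (young), 0 to 38 (Ki67-positive against quiescent), 0 to 3 (old), 0 to 13 (young), 0 to 1 (old against young, reactivated), 0 to 10 (Ki67-positive), 199 to 2462 (reactivated against Ki67-positive) and 6680 to 7594 (quiescent against guide library). In vivo the gene ranges were 6 to 9 (Top10), 0 to 7 (Depleted), 1 to 7 (glucose), 4 to 9 (ribonucleoprotein), 1 to 10 (published) and 9 to 10 (WT), and the guide ranges 8 to 78 (ribonucleoprotein), 0 to 45 (published) and 33 to 123 (WT).

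On summed counts DESeq2 called 1068, 1525 (old), 5 (young), 2993 (old against young, reactivated) and 2173 (reactivated against Ki67-positive). Control scaling gave 207, 57 (old), 17 and 417 for the same comparisons without young, limma 1 (young) and 37 (reactivated against Ki67-positive), and the compared groups only 9670 (quiescent against guide library). For guide sets, draws from all guides gave 1092, 32 (old), 1506 (young), 3 (Ki67-positive against quiescent) and 155 (reactivated against Ki67-positive). Safe-targeting guides gave 26 (old), 0 (Ki67-positive, old) and 658. Pool centring gave 2 (Ki67-positive, old), 1 (young) and 229 (quiescent against guide library). For Ki67-positive cells the compared groups gave 50, 29 (old) and 2 (young) and the filter at 1 count per 1000000 gave 1 (young). Without these 2 libraries 312 (reactivated, old), 40, 0 (old) and 3 (young) were called. With the highest guide left out 8 lists shifted. In vivo, other genes' guides as the null left 0 genes (Top10, Depleted, ribonucleoprotein, published, WT) and 1 (glucose). A pseudocount of 10 gave 0 (Depleted), 1 (glucose) and 5 (published), a pseudocount of 0.5 gave 2 (Depleted). Summed counts gave 6, 1 and 5, and a minimum of 50 counts 0 (WT). For guides, TMM gave 0 (Depleted), 0 (ribonucleoprotein) and 5 (WT), DESeq2 31 (Top10), 39 (ribonucleoprotein), 65 (published) and 102 (WT).

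With the screen number as a replicate block, guide sets gave 1 (Ki67-positive against quiescent), 3 (reactivated, old) and 0 (Ki67-positive, old), and in vivo guides 11 (ribonucleoprotein) and 25 (WT); 10 lists shifted by fry, and Slc2a4 turned to a mean score of -0.085. Beyond these and the values given in the report, the block changed no other call named there. Camera with an estimated correlation went from 9 lists to 0 (reactivated against quiescent) and from 12 to 0 (young), and with its preset from 7 to 3 (Ki67-positive against quiescent) and from 6 to 3 (old). No block was fitted for the guide library or for Top10, Depleted and glucose, whose subventricular zone reference carries the label 1/2; in the other in vivo gene tests the block gives the same value.

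The values that follow are mean guide scores (culture) or mean log2 differences (in vivo) relative to the null guides. Slc2a4, not called in any of these, changed sign in reactivated against quiescent cells with the compared groups only (-0.002), without these 2 libraries (-0.067) and without old reactivated replicate 3 (-0.201), young quiescent replicate 1 (-0.03) or young reactivated replicate 3 (0.0); the highest value without a library was 0.188. In old cells it did so with the filter at 1 count per 1000000 (0.041), draws from all guides (0.112), safe-targeting guides (0.028), pool centring (0.015) and without old reactivated replicate 1 (0.197) or 2 (0.084), against -0.206 without replicate 3. In young cells it did so with that filter (0.068), all guides (0.229), safe-targeting guides (0.08), without these 2 libraries (0.005), young quiescent replicate 2 (0.006) or young reactivated replicate 1 (0.058) or 3 (0.005), against -0.04 without young quiescent replicate 1. Against Ki67-positive cells it turned without old reactivated replicate 3 (-0.085, against 0.461 without replicate 1) and without these 2 libraries (-0.008). In young cells Olfr1299 (-0.008) turned without young reactivated replicate 3, against 0.806 without replicate 2. In vivo, other genes' guides as the null turned AA986860 (-2.53), B3GALNT2 (-1.58), FAM53C (-2.58) and RASSF8 (-0.07) in Top10 and SLC45A4 (-0.16) and SNRPB2 (-1.49) in the glucose sublibrary. It also turned CNOT3 (-4.72), DIS3L2 (-0.6), GRB7 (-1.21), PAPPA2 (-0.24), RBPMS (-0.71). Of published regulators it turned Bmpr1a (-0.13), Bmpr2 (-0.16), Cdkn1a (-0.82), Id4 (-0.46), Olig2 (-0.11) and Sox2 (-0.65), and in the WT comparison AA986860 (-3.27), B3GALNT2 (-1.79), CCDC15 (-0.58) and FAM53C (-2.51). A minimum of 50 counts turned DEFA3 and DEFA17 (-0.51) and RPL32 (-0.11). Leaving out a bulb replicate turned DEFA3 and DEFA17 (-0.85 without replicate 2, 3.13 without replicate 1) and RPL32 (-0.46 without replicate 1, 4.18 without replicate 2). Without bulb replicate 1, SLC45A4 (-0.78), SLIT2 (-0.85), SNRPB2 (-1.29) and CNOT3 (-1.28) turned, against 4.92, 6.72, 3.01 and 3.13 without replicate 2, and CNOT3 turned without subventricular zone replicate 2 (-0.42).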

Other observations

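The shares of single guides and the identical counts were looked at only after the data were seen, with no tests; the tests of sublibrary genes in culture were planned, and the prediction for shared guides was written before its result. The sublibraries were chosen by the study, so their genes are not independent evidence. In culture, 6 of the 10 Depleted genes were lower in reactivated against quiescent cells (9 adjusted over the list alone) and 7 in young cells; Defa3 and Defa17, with the same values, are counted as 2 in each. In old cells 0 of the ribonucleoprotein and Top10 genes were called, and fry shifted each list up (adjusted p = 0.0474; 0.116 in camera with an estimated correlation). Between old and young reactivated cells the ribonucleoprotein list shifted up by fry (adjusted p = 0.00442, median log2 change 2.42 relative to all genes; 0.0751 in camera with an estimated correlation) with 0 genes called. Fry tests against no change, and the sums of all genes ran upward there, with 6214 genes higher and 1264 lower at an unadjusted p under 0.05.

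In most thin libraries a few guides took most of the counts, and the leading guides differ between libraries. A guide of SPP1 took 99.76% of the cortex at 24 h (95% Wilson interval 99.75 to 99.78), a control guide 44.79% of the bulb at 24 h (44.7 to 44.87), and a guide of FAM53C 21.3% of the cerebellum at 24 h (21.23 to 21.37). At 5 weeks a control guide took 56.05% of the cerebellum (55.95 to 56.14). The top 10 guides took 15.32% of the subventricular zone at 5 weeks (15.28 to 15.36), and in the published regulators 95.84% of bulb replicate 1 (95.79 to 95.89) and 88.08% of subventricular zone replicate 1 (88.01 to 88.14). Of the guides in the Depleted sublibrary, 4 pairs of DEFA3 and DEFA17, 5 pairs of VMN1R55 and VMN1R107 and a pair of RPLP1 have identical counts, so these are not separate measurements.

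A hypothesis was that guides counted under several genes fall at reactivation because they cut more sites. The 4666 guides counted under 2 or more genes had a median log2 change lower than the 205140 other targeting guides by a difference of -0.5 (permutation p = 1e-04, the smallest possible), which is consistent with it. Of genes with at least 50% of their guides shared, 565 of 1572 were called lower (35.9%), against 2157 of 21277 others (10.1%). Whether the added sites or the function of such gene families is the cause was not tested apart.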
